A study of Mus musculus with 15 samples.

How the data were processed

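Tumours were induced in mice carrying VilCreER by a single intraperitoneal injection of tamoxifen at 80 mg/kg, and tissue was taken at the clinical endpoint. RNA was extracted with RNeasy Micro columns, libraries were made with TruSeq RNA kits and sequenced on a NextSeq 500 with 2 reads of 36 cycles. The authors checked reads with FastQC 0.11.8, trimmed them with Trim Galore 0.6.4, aligned them to GRCm38 with HISAT2 2.1.0 and counted them per gene with featureCounts 1.6.4. The gene annotation, strand setting, handling of reads with several locations and any filter are not given in the sources used here. The deposited values are the authors' counts for 24774 genes in 15 libraries, used as they stand, and 201 genes had 0 counts in every library. All gene identifiers matched GENCODE mouse release 21, from which symbols, coordinates on GRCm38 and gene types were taken, and 11 identifiers that shared a symbol with a more abundant one had theirs extended. Because the strand setting is not stated, counts of a gene can include antisense reads.

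Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using TMM normalization, the filterByExpr filter by group and robust quasi-likelihood F tests, with the threshold at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. Tumours and organoids were fitted apart for the genotype comparisons, and together for the difference of the genotype effect and for organoids against tumours. Gene lists, 57 in number, were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data and with the rotation test fry. A list was tested where at least 3 of its genes were. Genes of a list were also adjusted over the list alone. DESeq2 1.42.0, limma voom with quality weights and the edgeR test against a minimum 1.5-fold change served as other tools. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

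Genes to be named followed a rule. Part (a) took Kras, Trp53, Notch1, Hras and Nras. Part (b) took up to 12 genes each way (6 for the difference of the genotype effect and for organoids against tumours) with the largest absolute log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM of at least 1, CPM ranges that do not overlap and no predicted name, or, where none passed, the 5 of smallest p each way that met the other conditions. For the difference of the genotype effect the condition on ranges was not applied, since it involves 4 groups. Part (c) took up to 4 members of smallest p of each list past the threshold, and always of the MPAS, Wnt target, stem cell, fetal-like and Notch target lists, of which a selection is printed. Xist, Tsix and Y-linked genes served only to check the labelled sex. A gene with 0 counts in a group is given against a floor of 3 counts over the group.

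The tests were tried on counts simulated with known changes, from the real means, library sizes and dispersions. Of genes changed 2-, 4- and 8-fold, edgeR recovered 1.5%, 49.3% and 83.3% in the tumour layout, 0%, 31.3% and 78.8% in the organoid layout, 0%, 26.9% and 45.5% for the difference of the genotype effect, and 28.4%, 74.6% and 89.4% for organoids against tumours. It called 5, 2, 3 and 7 unchanged genes and DESeq2 70, 84, 48 and 77. DESeq2 recovered 23.9%, 82.1% and 97%, then 14.9%, 71.6% and 92.4%, then 4.5%, 53.7% and 80.3%, and 49.3%, 92.5% and 97%, in the same order. Of 5 lists shifted 1.5-fold, camera called 5, 5, 4 and 5, and of 50 not shifted 0. Genes were drawn independently, so this 0 leaves correlated lists untested. No library was a copy of another, as all 105 pairs had a chi-squared per degree of freedom of 43.03 or more.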

Results

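RNA was sequenced from 15 libraries of small intestinal tumour material of mice. All mice carried a Cre recombinase active in the intestinal epithelium after tamoxifen, a mutant Kras allele that Cre activates, floxed p53 alleles and a Notch1 transgene. This genotype is called KPN. In KPNKF mice the remaining wild-type Kras allele was floxed as well, so that Cre removes it. There were 4 KPN tumours, 4 KPNKF tumours, 4 KPN tumour organoids and 3 KPNKF tumour organoids. An organoid is epithelium grown in culture from a primary tumour. Total counts per library (M, 1e6 counts) were 14.2 M to 49.6 M in KPN tumours, 40.1 M to 45.4 M in KPNKF tumours, 26.8 M to 29.4 M in KPN organoids and 25.2 M to 29.2 M in KPNKF organoids. Values were the deposited read counts per gene, as counts per 1e6 counts (CPM). Levels are means ± SD over libraries and log2 fold changes are given ± SE, positive where KPNKF was higher. Counting intervals and floors cover counting error only. The labels do not say which animal each organoid line came from, so the p-values measure differences between libraries taken as independent.

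The first question was whether the Kras transcript level followed the genotype at Kras (ENSMUSG00000030265, GRCm38 chromosome 6, 145216699 to 145250239, minus strand). Kras, the gene of the Ras GTPase altered in these mice, was read at a similar level in all groups. In tumours its level was 123 ± 29.9 CPM in KPN (n = 4) and 158 ± 15.2 CPM in KPNKF (n = 4), a log2 fold change of 0.36 ± 0.23 with an adjusted p of 0.639. In organoids it was 111 ± 22.3 CPM in KPN (n = 4) and 122 ± 20.9 CPM in KPNKF (n = 3), a log2 fold change of 0.14 ± 0.21 with an adjusted p of 0.971. KPN tumour 2 held 78.7 CPM of Kras, under the 134 to 141 CPM of the other KPN tumours, and without that library the tumour fold change was 0.18. The counts sum over both alleles and all exons. They do not tell a mutant from a wild-type transcript, nor a transcript that lacks a deleted exon. Trp53, the gene of p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), was at 27.3 ± 6.63 and 24 ± 9.56 CPM in the KPN and KPNKF tumours. In the organoids it was at 11.5 ± 3.25 and 7.39 ± 1.58 CPM, with adjusted p = 0.845 in tumours and 0.961 in organoids. Notch1 was at 33.9 ± 9.34 and 33 ± 1.03 CPM in tumours. In organoids it was at 151 ± 150 and 93.8 ± 77.3 CPM, where KPN libraries spanned 42.8 to 372 CPM and the fold change changed sign without KPN organoid 1 (-0.69 with it, 0.26 without) (adjusted p = 0.964 and 0.966). The other Ras genes, Hras and Nras, had tumour log2 fold changes of -0.45 ± 0.37 (-0.06 without KPN tumour 2) and 0.09 ± 0.20 and organoid values of 0.09 ± 0.22 and -0.04 ± 0.21, none past the threshold.

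**Figure D1:**
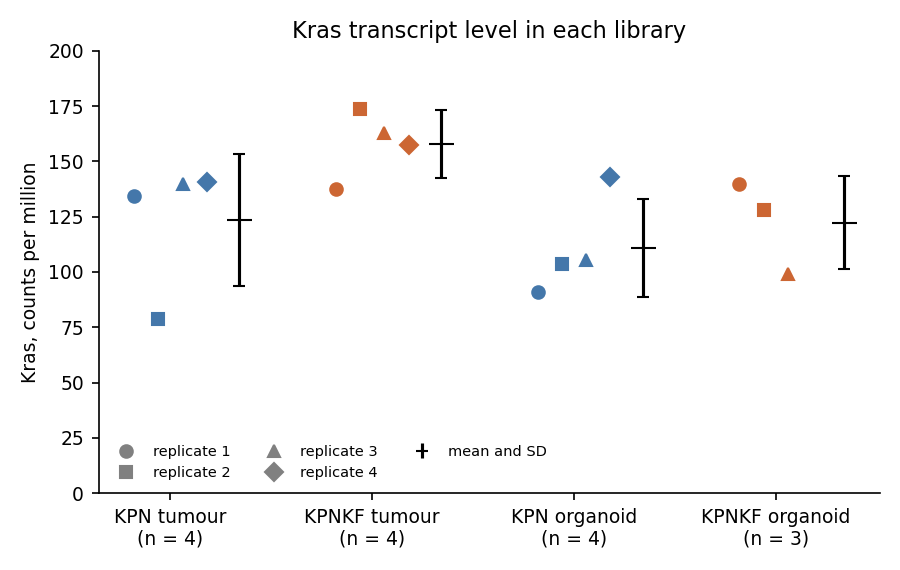
Kras transcript level in CPM (linear axis from 0) for each library of the 4 groups, with the marker shape giving the replicate number and black bars the mean and SD. The 4 KPNKF tumours lay between 138 and 174 CPM and the KPN tumours between 78.7 and 141 CPM, so the groups overlapped, as the organoid groups did.

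The tumours were compared to ask what the added loss of the remaining Kras allele went with in tumour tissue. As lists, and only with a preset correlation between genes, Wnt target, intestinal stem cell and proliferation genes were higher in KPNKF than in KPN tumours (adjusted p = 0.65 each with an estimated correlation). B and plasma cell, neutrophil, macrophage and T cell lists were lower (adjusted p = 0.65 to 0.662 with an estimated correlation), the T cell list not without KPN tumour 4 (0.0562). Of 20 Wnt target genes 19 had positive fold changes, with a median log2 fold change of 0.90, and all 32 proliferation genes were positive, with a median of 0.56. Of 24 B and plasma cell genes 23 were negative (median -1.22), as were 16 of 19 neutrophil genes (median -1.41) and 27 of 28 macrophage and monocyte genes (median -1.12). Without KPN tumour 1 the Wnt target median was 1.68, and without KPN tumour 2 the macrophage median was -0.56.

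No single gene of the 19757 tested passed the threshold in edgeR. In simulated counts of this layout edgeR recovered 1.5% of genes changed 2-fold, so the lack of calls does not show that single genes were unchanged. At an unadjusted p under 0.05 edgeR gave 1273 genes, 452 higher and 821 lower in KPNKF, where 988 would arise if none had changed, and the smallest adjusted p was 0.635. DESeq2 called 30 genes (16 higher and 14 lower), and limma voom with quality weights and the edgeR test against a minimum 1.5-fold change called 0 each. Without KPN tumour 1, edgeR called 1 gene, the predicted gene Gm830, which lies outside the rule for named genes and was picked after its value was seen (log2 fold change 3.23, adjusted p = 0.0358). Of the 57 gene lists 27 passed camera with a preset correlation, 13 higher and 14 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.65. The rotation test fry passed 0 lists (smallest adjusted p 0.524). Of the 35 splits of the tumour libraries, 15 gave 27 or more lists with a preset correlation, the real split included. Chance thus cannot be excluded for this count.

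Among single genes, the highest ranked by p with positive fold changes were Tgm4, a transglutaminase (1.04 ± 0.299 CPM in KPN against 8.23 ± 3.57 in KPNKF, log2 fold change 2.96 ± 0.46), and Glp1r, the receptor of the incretin GLP-1 (3.65 ± 1.68 against 29.4 ± 14.7 CPM, 3.01 ± 0.47). Mcpt4, a protease of mast cells, had a log2 fold change of 2.48 ± 0.48, the Myc family gene Mycl 1.79 ± 0.35 and the polyamine oxidase gene Paox 0.88 ± 0.17. On the other side stood Slpi, an inhibitor of neutrophil proteases (34.5 ± 17.7 against 8.44 ± 2.09 CPM, -2.03 ± 0.37), the lymphocyte phosphatase gene Ptpn22 (-1.67 ± 0.37), the neutrophil gene Retnlg (-1.64 ± 0.38), the B cell receptor gene Cd79b (-1.39 ± 0.33) and Ggct of glutathione turnover (-0.95 ± 0.24). These 10 genes, chosen for non-overlapping CPM ranges, each had an adjusted p of 0.635.

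The Wnt target list passed at an adjusted p of 1.35e-09, the proliferation list at 1.35e-09 and the stem cell list (15 of 20 positive, median 0.86) at 8.26e-08. Each stood at an adjusted p of 0.65 with an estimated correlation. The Wnt target and stem cell lists share members. Ascl2, a transcription factor of intestinal stem cells, was at 1.22 ± 0.577 CPM in KPN and 8.06 ± 4.6 CPM in KPNKF tumours (log2 fold change 2.70 ± 0.60). It was the 1 member of either list to pass when p was adjusted over the list alone, against 0 members over all genes. Rnf43 and Axin2, which restrain Wnt signalling, had fold changes of 1.63 ± 0.46 and 1.55 ± 0.67, and the receptor gene Ephb3 1.59 ± 0.69 (2.51 without KPN tumour 1). Slc12a2 and Cdca7 of the stem cell list had 1.13 ± 0.33 and 1.15 ± 0.36. Of the proliferation list, Rrm2 for nucleotide synthesis and Mcm4 of the replicative helicase had 1.13 ± 0.37 and 0.73 ± 0.26. In that list 0 members passed over all genes or adjusted over the list alone. KPN tumour 1 had a Wnt target score (mean log2 CPM) of 5.29, inside the 4.68 to 5.59 of the KPNKF tumours, and the other KPN tumours were at 2.24 to 4.09.

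The 10 genes of the MPAS score of Ras and MAPK output were all positive (median 0.70, 0.43 without KPN tumour 4 and 0.26 without KPN tumours 2 and 4, adjusted p = 0.000207), among them the receptor gene Epha2 (0.79 ± 0.25) and the feedback inhibitor gene Spry4 (0.72 ± 0.34). The list's adjusted p with an estimated correlation was 0.65. Its score was 4.32 in KPN tumour 4, 5.62 to 6.22 in the other KPN tumours and 6.09 to 6.43 in KPNKF, with KPN tumour 1 inside the KPNKF range. In it 0 members passed over all genes or adjusted over the list alone. Cholesterol synthesis genes were also higher, 23 of 25 (median 0.41, 0.12 without KPN tumour 2, adjusted p = 9.71e-05, and adjusted p = 0.683 with an estimated correlation). So were gastric and metaplastic genes, 13 of 19 (median 0.83, mean 0.34, adjusted p = 0.000522, and adjusted p = 0.65 with an estimated correlation), with 0 members of these lists past the threshold over all genes or adjusted over the list alone. The gastric median was 1.36 without KPN tumour 1, 0.38 without KPN tumour 3, 0.44 without KPN tumour 4 and 0.37 without KPNKF tumour 4. The fetal-like list was not called (median 0.07, mean -0.08, test direction up, adjusted p = 0.179), nor was the Notch target list (median -0.03, test direction up, adjusted p = 0.849), whose member of smallest p, Nrarp, had -1.02 ± 0.71, and 0.16 without KPN tumour 3. The median of the absorptive enterocyte list, -0.70, and the direction of its test, up, differed in sign (adjusted p = 0.544).

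On the lower side, the B and plasma cell list passed at an adjusted p of 4.99e-10, the macrophage and monocyte list at 2.97e-09 and the neutrophil list at 9.48e-07. Each had an adjusted p of 0.65 with an estimated correlation. Pax5 and Cd19, a regulator and a surface marker of B cells, had log2 fold changes of -2.76 ± 0.73 and -2.71 ± 0.75 from 1.01 ± 1.12 and 2.33 ± 2.64 CPM in KPN. Adjusted over the list alone 3 B and plasma cell genes and 2 neutrophil genes passed, against 0 over all genes, and 0 macrophage genes passed either way. Itgam and Tyrobp of myeloid cells had -1.30 ± 0.39 and -2.29 ± 0.92, the latter -0.64 without KPN tumour 2. Without KPN tumour 1, Pax5 had -1.57 and Cd19 -1.48. The T and NK cell list (28 of 32 negative, median -0.80) passed at 1.13e-05, or at an adjusted p of 0.662 with an estimated correlation, and its chemokine gene Ccl5 had -2.21 ± 0.60. This list was not called without KPN tumour 4 (median -0.40, adjusted p = 0.0562), and without KPNKF tumour 4 its median was -0.52. All 11 MHC class II genes were negative (median -0.68, -1.29 without KPNKF tumour 1, adjusted p = 0.000174, and adjusted p = 0.662 with an estimated correlation). In the T and NK cell and MHC class II lists 0 members passed over all genes or adjusted over the list alone. Immunoglobulin genes resemble each other in sequence, and how shared reads were counted is not stated.

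Metabolic and housekeeping lists were lower as well. All 37 ribosomal protein genes were negative, with Rpl32 at -1.92 ± 0.82 and Rps27 at -2.06 ± 0.74 (median -1.20, adjusted p = 9.06e-11, and adjusted p = 0.662 with an estimated correlation). Without KPN tumour 2 the median was -0.31, and Rpl32 had -0.38 and Rps27 -0.71. Nuclear genes of oxidative phosphorylation had 30 of 31 negative (median -0.58, adjusted p = 3.75e-09, and adjusted p = 0.65 with an estimated correlation). Their median was -0.23 without KPN tumours 2 and 4, which scored 7.73 and 7.95 against 6.86 and 7.53 in KPN tumours 1 and 3 and 6.91 to 7.14 in KPNKF. Glycolysis genes had 21 of 22 negative (median -0.40, adjusted p = 0.0015, and adjusted p = 0.65 with an estimated correlation), with Gpi1, an enzyme of the pathway, at -0.70 ± 0.27. Glycolysis was the 1 list of 57 whose scores did not overlap between the groups, at 6.94 to 7.07 in KPNKF and 7.22 to 7.5 in KPN, where chance gives 2.9% of lists or 1.6. Histone genes had 11 of 12 negative, with Hist1h1e at -3.47 ± 1.24 (median -0.93, adjusted p = 0.00086, and adjusted p = 0.65 with an estimated correlation). Without KPN tumour 2 this call was lost (median -0.53, adjusted p = 0.0565) and Hist1h1e had -1.11. In none of these lists did a member pass over all genes or adjusted over the list alone. Ribosomal protein genes have many near-identical pseudogenes that share their reads.

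Some lists depended on single tumours. All 11 distal small intestine genes were negative (median -1.98, adjusted p = 0.00335, and adjusted p = 0.683 with an estimated correlation). The ileal bile acid binding gene Fabp6 had -9.49 ± 2.98 because KPN tumour 3 held 609 CPM and the other KPN tumours at most 0.802 CPM, and without that library it was -0.82. The call was lost without KPN tumour 3 (median -1.31, adjusted p = 0.241) or KPN tumour 4 (0.159). Osr2 of the same list had -2.86 ± 1.10. Fatty acid oxidation genes were lower (25 of 26 negative, median -0.72, adjusted p = 0.00804, and adjusted p = 0.723 with an estimated correlation). They lost the call without KPNKF tumour 1 (0.0527) or 2 (0.072) and changed direction without KPN tumour 4 (median -0.01, adjusted p = 0.703). Antimicrobial genes, with Reg3b at -2.08 ± 1.07, were lower (17 of 20 negative, median -0.91, adjusted p = 0.0118, and adjusted p = 0.65 with an estimated correlation). They lost the call without KPN tumour 3 (median -0.55, adjusted p = 0.291). Interferon response genes were lower (26 of 37 negative, median -0.30, adjusted p = 0.00283, and adjusted p = 0.692 with an estimated correlation), a call lost without KPNKF tumour 3 (median -0.11, adjusted p = 0.0784), and without KPNKF tumour 1 their median was -0.62. Mast cell and eosinophil genes were higher (10 of 16 positive, median 1.00, adjusted p = 0.0111, and adjusted p = 0.662 with an estimated correlation), a call lost without KPN tumour 4 (0.0584) or KPNKF tumour 1 (0.127). Their protease genes Mcpt4 and Mcpt2 were positive, the latter at 2.30 ± 0.95. Without KPN tumour 1, Mcpt2 had 3.59. Adjusted over the list alone 1 member passed upwards and 1 downwards. Enteric glia and neuron genes were higher (13 of 20 positive, median 0.49, adjusted p = 0.00987, and adjusted p = 0.65 with an estimated correlation). That call was lost without KPN tumour 3 (median 0.31, adjusted p = 0.0673) or KPNKF tumour 1 (0.0505). Myc target and ribosome biogenesis genes were higher (23 of 30 positive, median 0.23, adjusted p = 0.00552, and adjusted p = 0.723 with an estimated correlation). That call was lost without KPN tumour 4 (median 0.12, adjusted p = 0.217) or KPNKF tumours 2 (0.0637) or 3 (0.0513). In the other lists of this kind 0 members passed over all genes or adjusted over the list alone.

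Of the remaining lists past the threshold, ErbB ligands and receptors were higher (10 of 14 positive, median 0.12, adjusted p = 0.0111, and adjusted p = 0.65 with an estimated correlation). The ligand gene Btc had 1.45 ± 0.41, and the call was lost without KPN tumour 2 (0.0512) or 4 (0.0506). Junction and keratin genes had a median of 0.09 (adjusted p = 0.0305, and adjusted p = 0.733 with an estimated correlation). They changed direction without KPN tumour 2 (0.742). They also lost the call without KPN tumour 1 (0.219) or KPNKF tumours 2 (0.0795) or 4 (0.0536). Other ERK target genes had a median of 0.17 (adjusted p = 0.0404, and adjusted p = 0.683 with an estimated correlation). They lost the call without KPN tumours 3 (0.0673) or 4 (0.794) or KPNKF tumours 1 (0.0848) or 4 (0.0536), or with labelled sex in the model (0.0678). Metastasis-associated ligands and receptors had a median of 0.20 and a mean of 0.01 (adjusted p = 0.0381, and adjusted p = 0.683 with an estimated correlation). Their call was lost without KPN tumours 2 (0.0523) or 4 (0.669) or KPNKF tumours 1 (0.118) or 2 (0.0559), or with labelled sex in the model (0.0509). NF-kB and inflammatory cytokine genes had a median of -0.41 (adjusted p = 0.0366, and adjusted p = 0.723 with an estimated correlation). Their call was lost without KPN tumours 1 (0.769), 2 (0.13) or 3 (0.175) or KPNKF tumours 3 (0.0784) or 4 (0.151). Without KPN tumour 1 the medians were 0.47 for ErbB, 0.35 for other ERK target, 0.45 for metastasis-associated and 0 for junction genes. Without KPN tumour 2 that of junction genes was -0.09, and without KPN tumour 3 it was 0.29 and that of metastasis-associated genes 0.12. Without KPN tumour 4 they were 0.24 for ErbB, 0.04 for other ERK target, 0.26 for junction and -0.65 for NF-kB genes. Without KPNKF tumour 1 they were 0.27 for ErbB, 0.18 for junction and -0.63 for NF-kB genes, and without KPNKF tumour 2 0.05 for junction genes.

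KPN tumours 2 and 4 stood apart in what their RNA held. In KPN tumour 2, 27.6% of the counts lay in 5 genes, the ribosomal RNA gene CT010467.1 (13.84%), the protein-coding Lars2 (9.16%), Gm23935 (1.24%) and the mitochondrial ribosomal RNA genes mt-Rnr1 (1.48%) and mt-Rnr2 (1.90%), against at most 1.46% for the 5 in every other library. Its ribosomal protein score was 9.95 against 7.34 to 8.37 in the other tumours. Its enterocyte score was 1.08, that of KPN tumour 4 was 10.18, and those of the other tumours were 7.1 to 8. With both left out, an alternative chosen after seeing the data, edgeR again called 0 genes and 32 lists passed, 13 higher and 19 lower. The medians were then 0.37 for Wnt target, 0.31 for stem cell, 0.31 for proliferation and 0.26 for MPAS genes. They were -1.36 for B and plasma cell, -1.58 for neutrophil, -0.75 for macrophage, -0.60 for T and NK cell and -0.39 for ribosomal protein genes. These 9 lists passed the threshold with a preset correlation. The MHC class II (0.0804), ErbB (0.219), fatty acid oxidation (0.746), junction (0.754), metastasis-associated (0.754) and other ERK target (0.849) lists were not called without these libraries, each value being an adjusted p. The metastasis-associated list then had the opposite direction. KPN tumour 1 resembled the KPNKF tumours, with a correlation (Pearson's r of log2 counts across genes) of 0.958 to 0.976 with them, where they had 0.96 to 0.981 among themselves, and of 0.837 to 0.933 with the other KPN tumours. Without it 3490 genes had an unadjusted p under 0.05, against 1273 with it.

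**Figure D2:**
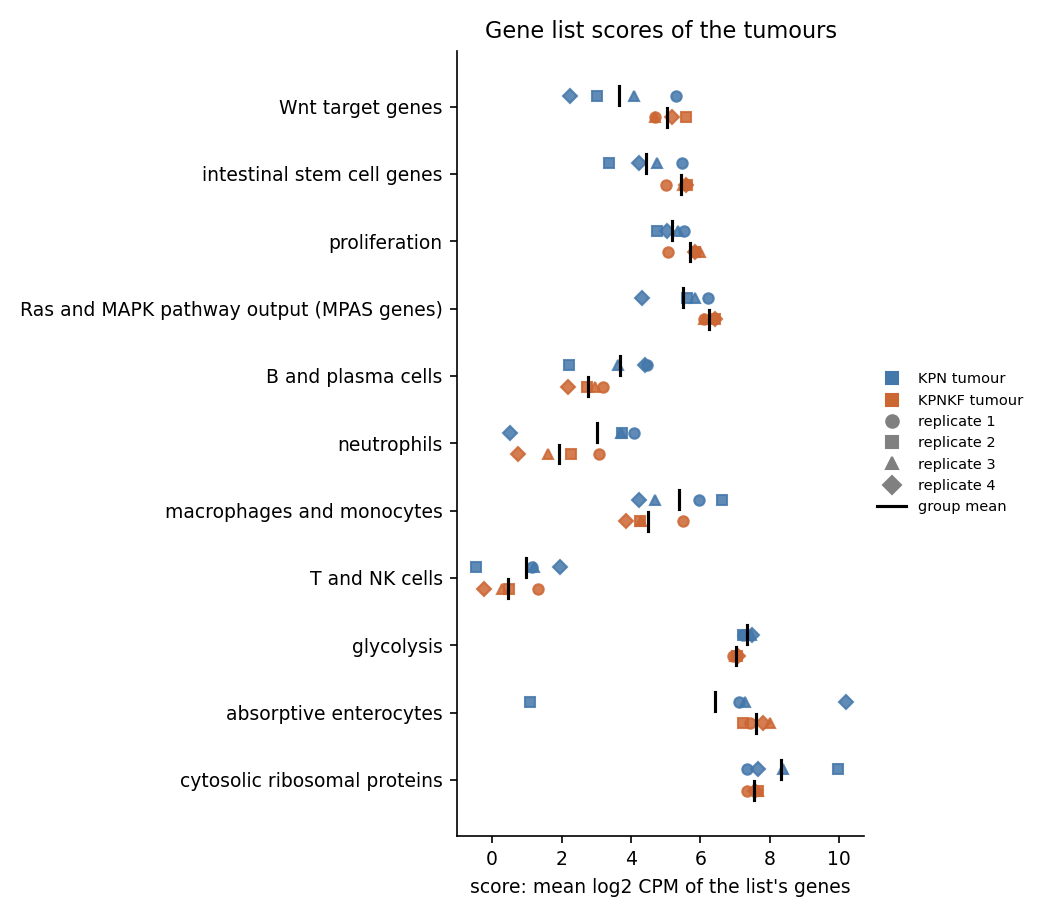
Score of each gene list (mean log2 CPM of its genes, horizontal axis) in each of the 8 tumour libraries, with KPN and KPNKF in separate colours, marker shapes for replicate numbers and black lines for group means. KPNKF scores spanned 4.68 to 5.59 for Wnt target genes against 2.24 to 5.29 in KPN, and KPN tumours 2 and 4 lay at 1.08 and 10.18 for absorptive enterocyte genes.

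The organoids were compared to ask what the same genotype difference went with in epithelium free of stroma. Lists of differentiated intestinal epithelium were higher in KPNKF than in KPN organoids with a preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.178 to 0.325 for the 4 lists that follow). Absorptive enterocyte genes had a median log2 fold change of 1.05 (11 of 15 positive), goblet cell genes 1.49 (12 of 16), Paneth cell genes 2.12 (6 of 9) and proximal small intestine genes 1.59 (7 of 9). The enterocyte median was 1.59 without KPNKF organoid 3. The scores of these 4 lists were higher in each of the 3 KPNKF organoids than in each of the 4 KPN organoids. Levels stayed low, since the enterocyte score was -0.15 to 0.41 in KPNKF and -1.56 to -0.75 in KPN organoids, on the log2 CPM scale.

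Of 16402 genes tested, edgeR called 0, with 800 at an unadjusted p under 0.05 (534 higher and 266 lower, where 820 would arise if none had changed) and a smallest adjusted p of 0.123. DESeq2 called 118 genes (94 higher and 24 lower), and limma voom with quality weights and the edgeR test against a minimum 1.5-fold change called 0 each. Without KPN organoid 4 edgeR called 21 genes, 16 higher and 5 lower. With all 15 libraries in a single fit it called 2 genes, Itga1 (3.26, adjusted p = 0.00051) and Mafb (-5.89, adjusted p = 0.0237). Of the 56 lists with at least 3 genes tested, 15 passed camera with a preset correlation, 10 higher and 5 lower, and 24 passed without KPNKF organoid 2. With an estimated correlation 0 passed (smallest adjusted p 0.178). The rotation test fry passed 2, enterocytes and fatty acid oxidation, at an adjusted p of 0.0412 each.

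Itga1, the alpha subunit of a collagen-binding integrin (ENSMUSG00000042284, chromosome 13, 114953096 to 115101964, minus strand), had the smallest p. It was at 0.86 ± 0.134 CPM in KPN (n = 4) and 8.33 ± 1.15 CPM in KPNKF organoids (n = 3), a log2 fold change of 3.27 ± 0.30 with an adjusted p of 0.123. Sema4g, a semaphorin gene, followed at 36.4 ± 8.9 and 144 ± 32.9 CPM (1.98 ± 0.25, adjusted p = 0.525). Ppp1r14d, Gstp3 and Cideb had 3.73 ± 0.64, 3.67 ± 0.64 and 2.72 ± 0.48, each with an adjusted p of 0.945. With negative fold changes stood the transcription factor gene Mafb (9.7 ± 5.32 against 0.163 ± 0.0595 CPM, -5.86 ± 0.86) and the receptor kinase gene Kit (6.21 ± 1.99 against 0.259 ± 0.176 CPM, -4.57 ± 0.69), both at an adjusted p of 0.724. Cldn6, a claudin gene, had -6.67 ± 1.44 (0.945), Pxdn, which encodes a matrix peroxidase, -8.52 ± 1.97 (0.961), and Gbe1, a glycogen enzyme gene, -1.69 ± 0.42 (0.961). The CPM ranges of these 10 genes did not overlap between the groups.

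The enterocyte list passed at an adjusted p of 9.73e-08 (adjusted p = 0.178 with an estimated correlation) and the goblet cell list at 3.38e-07 (adjusted p = 0.325 with an estimated correlation). The proximal small intestine list passed at 9.94e-06 (adjusted p = 0.227 with an estimated correlation) and the Paneth cell list at 0.000113 (adjusted p = 0.325 with an estimated correlation). Adjusted over the list alone 2 enterocyte, 1 proximal, 1 Paneth and 0 goblet cell genes passed, against 0 over all genes. Fabp2, an intestinal fatty acid binding protein gene, was at 0.421 ± 0.366 CPM in KPN and 2.81 ± 0.517 CPM in KPNKF (2.72 ± 0.60). Aldob of fructose metabolism (6.51 ± 1.56), the brush border phosphatase gene Alpi (4.82 ± 1.59) and the carboxylesterase gene Ces2a (3.32 ± 1.09) were also positive. Of secretory cell genes, the mucin gene Muc13 had 4.77 ± 1.62, Tff3 of goblet cells 3.88 ± 1.39, the Notch ligand gene Dll4 2.12 ± 0.49 and the lysozyme gene Lyz1 of Paneth cells 3.28 ± 1.66. KPN organoid 4 was the highest of the KPN organoids for Fabp2, Aldob, Alpi, Muc13, Tff3 and Lyz1, at 0.97, 0.903, 1.44, 6.39, 1.27 and 2.67 CPM. Without it Muc13 had 7.29, and the fitted values of Alpi, Tff3 and Lyz1 were over 1.5 times as large but rest on levels of at most 0.0702 CPM in the other KPN organoids. Without KPNKF organoid 1 Muc13 had 2.95. In the enterocyte list KPN organoid 4 scored -0.75 against -1.56 to -1.35 in the other KPN organoids.

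Further lists were higher with a preset correlation. Junction and keratin genes were higher, 18 of 24 (median 0.35, 0.19 without KPNKF organoid 1, adjusted p = 3.81e-06, and adjusted p = 0.381 with an estimated correlation). The claudin gene Cldn15 had 3.71 ± 0.78 and the intestinal transcription factor gene Cdx1 4.65 ± 1.11, and 2 members passed adjusted over the list alone. Gastric and metaplastic genes were higher, 14 of 15 (median 1.59, adjusted p = 3.74e-05, and adjusted p = 0.502 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. Pgc, a pepsinogen gene (8.22 ± 2.04), the gland mucin gene Muc6 (3.49 ± 1.56) and Gkn3 (4.41 ± 1.99) led that list. Each spread widely among the KPNKF organoids, Pgc from 0.827 to 401 CPM. Without KPN organoid 4 the list's median was 2.41 and Gkn3 had 7.04, and without KPNKF organoid 2 the median was 0.58 and Muc6 had 2.00. Fatty acid oxidation genes were higher, 18 of 25 (median 0.27, 0.17 without KPN organoid 2, adjusted p = 0.000362, and adjusted p = 0.178 with an estimated correlation). Ehhadh had 2.18 ± 0.45 and Cpt1a, which admits fatty acids to mitochondria, 1.07 ± 0.35, and 2 members passed adjusted over the list alone. Unfolded protein and amino acid stress genes were higher, 23 of 26 (median 0.28, adjusted p = 0.00258, and adjusted p = 0.543 with an estimated correlation), with Chac1 at 0.50 ± 0.24. This call was lost without KPN organoid 2 (median 0.16, adjusted p = 0.0649) or KPNKF organoid 2 (0.17 and 0.195). Metastasis-associated ligands and receptors were higher, 15 of 21 (median 0.41, adjusted p = 0.024, and adjusted p = 0.522 with an estimated correlation). Their call was lost without KPN organoid 2 (median 0.13, adjusted p = 0.261) or KPNKF organoids 1 (0.183) or 3 (median 0.20, adjusted p = 0.088), or with labelled sex in the model (0.175). Pancreatic acinar genes, only 4 of them tested, had a median of 1.76 and a mean of 0.05 (adjusted p = 0.0132, and adjusted p = 0.453 with an estimated correlation). The call was lost without KPN organoid 2 (0.11) or KPNKF organoid 3 (median 1.16, adjusted p = 0.119), with 2 members past the threshold adjusted over the list alone.

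Notch target genes were lower, 11 of 12 (median -0.65, adjusted p = 0.03, and adjusted p = 0.613 with an estimated correlation). Hes7 had -1.34 ± 0.57 and Olfm4 -2.5 ± 1.26 (-1.45 without KPN organoid 2), with 0 members past the threshold adjusted over the list alone. This call was lost without KPN organoid 1 (0.132), 2 (0.139) or 3 (0.486) and without KPNKF organoid 2 (0.162) or 3 (0.119), each value being an adjusted p. The median was -0.43 without KPN organoid 1, -0.27 without KPN organoid 3, and -1.88, -0.23 and -0.37 without KPNKF organoids 1, 2 and 3. The mast cell and eosinophil list was lower (6 of 8 negative, median -1.79, adjusted p = 0.00031, and adjusted p = 0.227 with an estimated correlation). So was the pericyte and interstitial cell list (4 of 4 negative, median -0.76, adjusted p = 0.000592, and adjusted p = 0.325 with an estimated correlation). They share the gene Kit, and 1 member of each passed adjusted over the list alone. The mast cell median was -3.43 without KPNKF organoid 1, and the pericyte median -0.28 without KPN organoid 1 and -0.38 and -0.43 without KPNKF organoids 2 and 3. The protease gene Mcpt1 of the former had -4.30 ± 2.47, with 701 CPM in KPN organoid 3 and at most 45.5 CPM in the other KPN organoids. Without KPN organoid 3 it had -1.28, and without KPNKF organoid 1 -9.01. Ribosomal protein genes were lower, 34 of 37 (median -0.20, Rpl13 at -0.47 ± 0.17, adjusted p = 0.000955, and adjusted p = 0.809 with an estimated correlation), a call lost without KPN organoid 3 (median -0.09, adjusted p = 0.0687) or KPNKF organoid 1 (-0.12 and 0.165), and the median was -0.32 without KPNKF organoid 2. Heat shock genes were lower, 12 of 15 (median -0.17, Hsph1 at -1.42 ± 0.58, or -0.85 without KPN organoid 2, adjusted p = 0.0298, and adjusted p = 0.381 with an estimated correlation), a call lost without KPN organoid 2 (0.0661) or KPNKF organoids 1 (0.0776) or 3 (0.124). Their median was -0.28 without KPN organoid 4 and -0.29 and -0.08 without KPNKF organoids 2 and 3. With labelled sex in the model, which was unevenly spread (female were KPN organoid 4 and KPNKF organoids 1 and 3), 12 lists passed. Of the 5 lower lists, Notch target (0.22), ribosomal protein (0.16) and heat shock genes (0.147) were then not called.

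The stem cell list was not called in organoids (median 0.17, adjusted p = 0.0987), nor were the Wnt target (median 0.02, mean -0.16, test direction up, 0.705), fetal-like (0.24, adjusted p = 0.289), proliferation (0.02, adjusted p = 0.916) and MPAS lists (-0.09, adjusted p = 0.788). Their members of smallest p included Ascl2 (2.5 ± 1.30, and 4.67 without KPN organoid 4), Ephb2 (1.79 ± 0.58), the tissue factor gene F3 (2.08 ± 0.46), Ankrd1 (-1.41 ± 0.39) and the cyclin gene Ccnd1 (-0.56 ± 0.36, and -0.23 without KPN organoid 1), none past the threshold. Scores did not overlap between the groups for 9 of the 56 lists, 8 higher and 1 lower in KPNKF, where chance gives 5.7% or 3.2 lists.

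**Figure D3:**
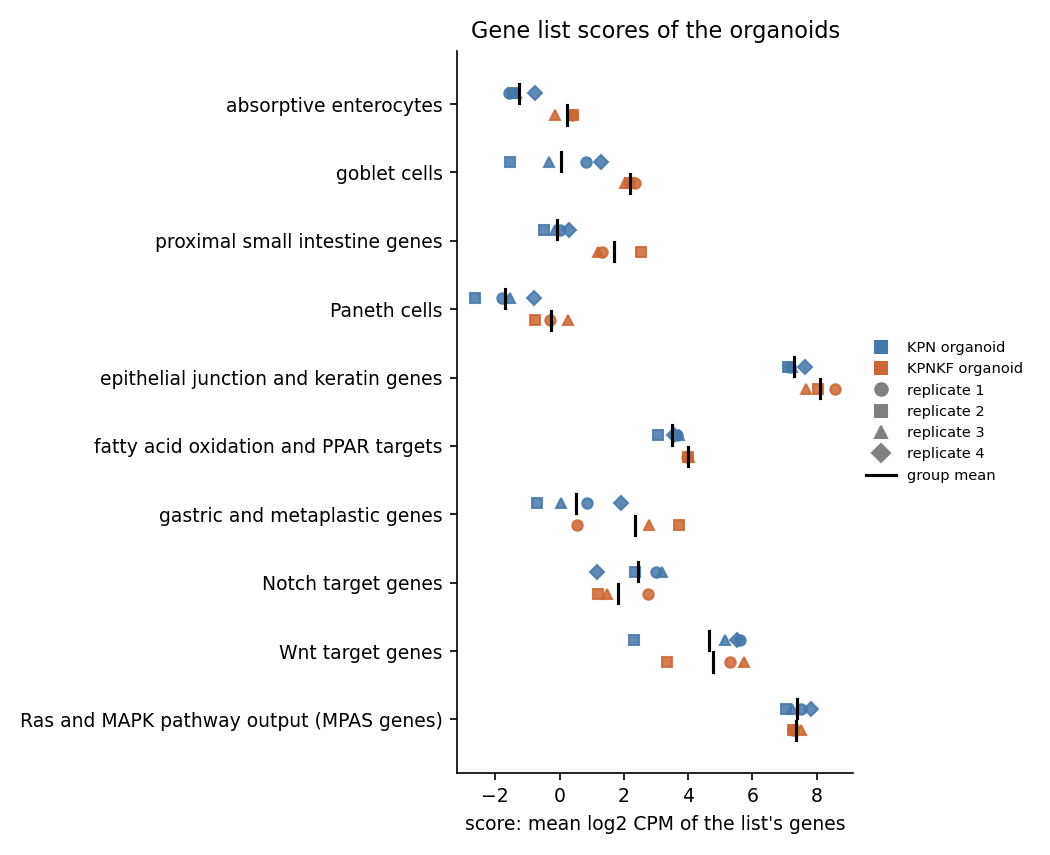
Score of each gene list (mean log2 CPM of its genes, horizontal axis) in each of the 7 organoid libraries, with KPN and KPNKF in separate colours, marker shapes for replicate numbers and black lines for group means. The 3 KPNKF organoids scored -0.15 to 0.41 for absorptive enterocyte genes, above the -1.56 to -0.75 of the KPN organoids, and the groups overlapped for Wnt target and MPAS genes.

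Whether the same genes moved with the genotype in tumours and organoids was asked across the 15995 genes tested in both. The log2 fold changes correlated across genes with Pearson's r of 0.106 and Spearman's rho of 0.091, and genes are not independent replicates. Of the 35 splits of the organoid libraries into 4 and 3, 11 gave an r at least as high (permutation of labels, 1-sided, range -0.198 to 0.181). The coefficient was 0.017 without KPN tumour 2, 0.07 without KPN tumour 3, 0.203 without KPN tumour 4 and 0.01 without KPN organoid 3. No gene was called in both by edgeR or by DESeq2. At an unadjusted p under 0.05 in both, 9 genes were higher in both (12.7 expected) and 10 were lower in both (10.2 expected), with 1-sided hypergeometric p of 0.893 and 0.571. Rpl13 of the ribosome was among the genes lower in both. Another 10 genes went opposite ways, and since no expected count was computed for these, they cannot be weighed against the shared ones.

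The difference of the genotype effect between organoids and tumours was tested directly, with positive values where the effect was higher in organoids. Goblet cell, enterocyte and fatty acid oxidation genes had the more positive effect in organoids, and Wnt target, MPAS and proliferation genes the more positive effect in tumours, as lists with a preset correlation. With an estimated correlation their adjusted p was 0.748 to 0.846, and the enterocyte (0.868) and fatty acid oxidation (0.145) calls were lost without KPN tumour 4. The median difference was 1.64 for 19 goblet cell, 2.82 for 30 enterocyte, -0.96 for 20 Wnt target and -0.49 for 32 proliferation genes. The enterocyte median was 1.08 without KPN tumour 4, and many enterocyte genes failed the organoid count filter. Without KPNKF organoid 3 the Wnt target and proliferation medians were -1.47 and -0.74. The former was -1.83 without KPN tumour 1, the latter -0.31 without KPN organoid 1. Itga1, with the smallest p, was at 0.85 ± 0.135 and 8.15 ± 1.11 CPM in KPN and KPNKF organoids and at 72.9 ± 31.3 and 101 ± 14 CPM in the tumours (difference 2.79 ± 0.37, adjusted p = 0.0716). Of 20047 genes, edgeR called 0, with 1353 at an unadjusted p under 0.05 (883 positive and 470 negative, 1002 expected if none had changed), and DESeq2 called 57 (45 and 12). Without KPN organoid 4 edgeR called 25 genes, and without KPN tumour 1 or KPN tumour 3 it called Itga1 alone (2.45, adjusted p = 0.0148, and 2.94, adjusted p = 0.0347).

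Mafb (-5.17 ± 0.87) and Kit (-4.59 ± 0.82) had an adjusted p of 0.384, and Kit was at 17.3 ± 8.7 and 17.2 ± 8.38 CPM in KPN and KPNKF tumours. Gstp3 (4.85 ± 0.97) and Pxdn (-8.68 ± 1.72) stood at 0.728, and Tstd1 (3.72 ± 0.80), Flot1 (1.39 ± 0.31), Bcl7a (-1.27 ± 0.32) and Hells, a chromatin remodeller gene (-1.85 ± 0.50), at 0.729. Atoh1, the transcription factor gene of secretory cells, had 5.66 ± 1.27, but KPN organoids held only 2 counts of it against 66 in KPNKF organoids, a ratio of 48.9 with a counting interval of 13.5 to 404.

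Of the 57 lists 20 passed camera with a preset correlation, 13 positive and 7 negative, and 13 passed without KPN tumour 4. Camera with an estimated correlation passed 0 (smallest adjusted p 0.748), as did fry (0.666). Goblet cell genes (16 of 19 positive) passed at 3.75e-08 (adjusted p = 0.748 with an estimated correlation), with 5 members past the threshold adjusted over the list alone and 0 over all genes. Tff3 had 4.84 ± 1.19, a value over 1.5 times as large without KPN organoid 4, where few counts are left in KPN organoids. Proliferation genes (30 of 32 negative) passed at 9.14e-06 (adjusted p = 0.846 with an estimated correlation), with Mcm4 at -1.16 ± 0.39 and Rrm2 at -0.97 ± 0.44. Wnt target genes (19 of 20 negative) passed at 0.00136 (adjusted p = 0.846 with an estimated correlation), with Nkd2 at -3.34 ± 1.64 (-2.08 without KPNKF tumour 1), and lost the call without KPNKF organoid 2 (0.0789). MPAS genes (9 of 10 negative, median -0.72) passed at 0.0045 (adjusted p = 0.748 with an estimated correlation), with Dusp4 at -1.07 ± 0.58, and lost it without KPN organoid 4 (median -0.33, adjusted p = 0.0632) or KPN tumour 4 (-0.38 and 0.092). Enterocyte genes (28 of 30 positive) passed at 0.0012 (0.846 with an estimated correlation), with Aldob at 6.98 ± 1.85. Fatty acid oxidation genes (median 0.83) passed at 0.000108 (0.748 with an estimated correlation). Without KPN tumour 4 these lists stood at 0.868 and 0.145, the latter with a median of 0.50. Ribosomal protein genes (37 of 37 positive, median 0.88) passed at 3.15e-05 (0.846 with an estimated correlation). They lost it without KPN tumour 2 (median 0.14, adjusted p = 0.861). In the proliferation, Wnt target, MPAS, enterocyte, fatty acid oxidation and ribosomal protein lists 0 members passed adjusted over the list alone.

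The organoids and tumours were compared to describe what each sample type held, in 1 fit of all 15 libraries with both genotypes weighted equally. Organoids lacked the RNA of stroma, vessels, blood and immune cells that the tumours held, and also most RNA of differentiated epithelium. Fibroblast and matrix genes had a median log2 fold change of -9.89, macrophage genes -7.90, endothelial genes -6.64 and absorptive enterocyte genes -9.35. These 4 lists passed camera with a preset correlation only (adjusted p = 0.17, 0.187, 0.0634 and 0.403 with an estimated correlation). Organoids held more RNA of stress response, Myc target, proliferation, glycolysis and MPAS genes, with medians of 2.03, 0.93, 0.86, 1.33 and 1.49. Of these 5 lists the stress response list passed camera with an estimated correlation as well (adjusted p = 0.0278), and the others with a preset correlation only (0.323, 0.388, 0.224 and 0.196 with an estimated one). Organoids and tumours also differ in name series, and sequencing runs are not stated.

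Of 20047 genes edgeR called 10626, with 4370 higher in organoids (41.1%) and 6256 lower. DESeq2 called 12712, and edgeR called 8350 within KPN and 6248 within KPNKF. With the size factors of DESeq2 in edgeR's form (RLE) the median log2 fold change of all genes moved by -0.063 and 37.2% of the calls were higher. Among genes higher in organoids with non-overlapping ranges, the largest change was in Adm2, a peptide hormone gene (0.518 ± 0.544 CPM in tumours, n = 8, and 70.9 ± 34.4 CPM in organoids, n = 7, log2 fold change 7.51 ± 0.45). Aldh1l2 of mitochondrial folate metabolism (5.54 ± 0.63), the glutathione-degrading Chac1 (5.34 ± 0.35), the pseudokinase gene Trib3 (5.16 ± 0.29), the ephrin gene Efna3 (4.65 ± 0.64) and the stress cytokine gene Gdf15 (4.60 ± 0.68) followed, with adjusted p of 0.000102 or less. Efna3 had 3.78 without KPNKF organoid 1 and Gdf15 3.85 without KPN organoid 4. Igha, the constant region of immunoglobulin A, fell from 4290 ± 4340 CPM to 5 counts over all organoids (-17.07 ± 1.55). The liver-type fatty acid binding gene Fabp1 fell from 1440 ± 2400 to 0.163 ± 0.413 CPM (-15.10 ± 2.29, or -13.71 without KPN tumour 4). Most of its organoid counts lay in KPNKF organoid 2, without which the fitted fall was larger. Sparcl1, Iglc1 and Cyp3a25 had 0 counts in all organoids and were at least 13500-fold, 13100-fold and 8980-fold lower, against a floor of 3 counts over the group. KPN tumour 4 held 773 CPM of Cyp3a25 and the other tumours 0.0977 to 127 CPM, and without that library the bound was 2980-fold. H2-Aa of MHC class II had 1 count over all organoids, a ratio of tumours to organoids of 63000 with a counting interval of 11300 to 2490000. That count lay in KPN organoid 4, and without this library all organoids held 0.

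Of the 57 lists 39 passed with a preset correlation, 11 higher and 28 lower in organoids, and fry passed 42. Camera with an estimated correlation passed 2, both at an adjusted p of 0.0278. Unfolded protein and amino acid stress genes were higher, with 19 members higher and 1 lower of 26, and 20 and 3 adjusted over the list alone. Red blood cell genes were lower (median -6.77, or -6.66 with genes of 0 counts at their bound), with 8 of 8 members lower over all genes and adjusted over the list alone. The lists of this paragraph had an adjusted p of 2.63e-21 to 5.18e-07 with a preset correlation, and the adjusted p with an estimated correlation follows each member count. All 11 MHC class II genes fell (0.17), as did 28 of 32 fibroblast and matrix genes (0.17), with Col3a1, a fibrillar collagen gene, at -12.17 ± 0.75. Endothelial genes had 22 lower and 1 higher of 26 (0.0634), with the vessel gene Plvap at -7.29 ± 0.31, macrophage genes 24 lower of 27 (0.187), and B and plasma cell genes 21 lower and 1 higher of 24 (0.162, median -8.02, or -6.79 at the bounds). T and NK cell genes had 30 lower of 33 (0.196, median -6.00, or -5.86 at the bounds) and smooth muscle genes 18 lower of 21 (0.187, median -7.34, or -7.01 at the bounds). Of epithelial lists, 30 of 30 enterocyte genes fell (0.403), with Apoa1 and Sis, a lipoprotein and a brush border disaccharidase gene, at -13.17 ± 1.51 and -13.50 ± 1.65. Sis had -12.74 without KPN tumour 4, -14.16 without KPN organoid 4 and -14.78 without KPNKF organoid 2. So did 15 of 19 goblet cell genes (0.196), with the mucin gene Muc2 at -9 ± 0.81, and 21 of 26 enteroendocrine genes (0.224), with Chga at -8.27 ± 0.90 (-7.45 without KPN tumour 4, -9.18 without KPN organoid 3). Their counts adjusted over the list alone were the same, except 19 for smooth muscle. All 15 mitochondrially encoded transcripts fell (0.196, median -2.13), mt-Atp6 at -2.45 ± 0.23, both over all genes and adjusted over the list alone.

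On the higher side, proliferation genes had 22 of 32 higher (adjusted p = 2.77e-07, and adjusted p = 0.388 with an estimated correlation), with the mitotic kinase gene Aurka at 1.88 ± 0.24, and Myc target genes 24 higher and 1 lower of 30 (adjusted p = 4.45e-07, and adjusted p = 0.323 with an estimated correlation). Glycolysis genes had 14 higher and 1 lower of 22 (adjusted p = 7.18e-06, and adjusted p = 0.224 with an estimated correlation), with Pkm at 1.75 ± 0.22, and MPAS genes 8 of 10 higher (adjusted p = 7.95e-05, and adjusted p = 0.196 with an estimated correlation), with Epha2 at 2.5 ± 0.26 and the phosphatase gene Dusp4 at 2.49 ± 0.30. Squamous and basal keratin genes had 10 higher and 1 lower of 15 (median 2.41, adjusted p = 0.0075, and adjusted p = 0.392 with an estimated correlation), with the plakophilin gene Pkp1 at 2.32 ± 0.35, and fetal-like genes 11 higher and 3 lower of 28 (median 0.79, 0.51 and 0.50 without KPNKF organoids 1 and 3, adjusted p = 0.0196, and adjusted p = 0.509 with an estimated correlation). The counts of these 6 lists were the same adjusted over the list alone. Myc itself was higher by 1.96 ± 0.23. The Wnt target list was not called (median 0.89, adjusted p = 0.0793), while its Sox9 was higher (1.51 ± 0.28). Not called either were the stem cell list (median 0.39, mean -0.49, test direction up, adjusted p = 0.657) and the Notch target list (median 0.09, mean -0.69, test direction down, adjusted p = 0.856), of which Olfm4 (-4.97 ± 1.05, or -4.29 without KPN tumour 4) and Hey2 (-3.93 ± 0.56) fell. Proximal small intestine genes were lower (median -6.07, adjusted p = 0.0351, and adjusted p = 0.478 with an estimated correlation), a call lost without KPNKF organoid 1 (0.0583) or 3 (0.0568).

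Other lists past the threshold are given as counts of members, followed by the adjusted p with a preset and with an estimated correlation. Lower in organoids were 13 of 15 dendritic cell genes (adjusted p = 5.28e-07, and adjusted p = 0.187 with an estimated correlation), 14 of 20 enteric glia and neuron genes (6.74e-05 and 0.196) and 26 of 37 interferon response genes (7.29e-05 and 0.458). Neutrophil genes had 15 lower and 1 higher of 19 (6.52e-06 and 0.323), pericyte and interstitial cell genes 8 and 1 of 10 (5.29e-05 and 0.187) and mast cell and eosinophil genes 13 and 1 of 17 (0.000274 and 0.196). Paneth cell genes had 13 lower of 17 (0.0117 and 0.458, median -6.10, or -5.79 at the bounds). Higher in organoids were 11 of 37 ribosomal protein genes (6.74e-05 and 0.537, and 8 members adjusted over the list alone) and 10 immediate early genes of 19, with 1 lower (0.00117 and 0.224). Adjusted over the list alone, interferon response genes had 27 lower and 1 higher and immediate early genes 11 higher and 1 lower, and the other 6 lists had the same counts.

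**Figure D4:**
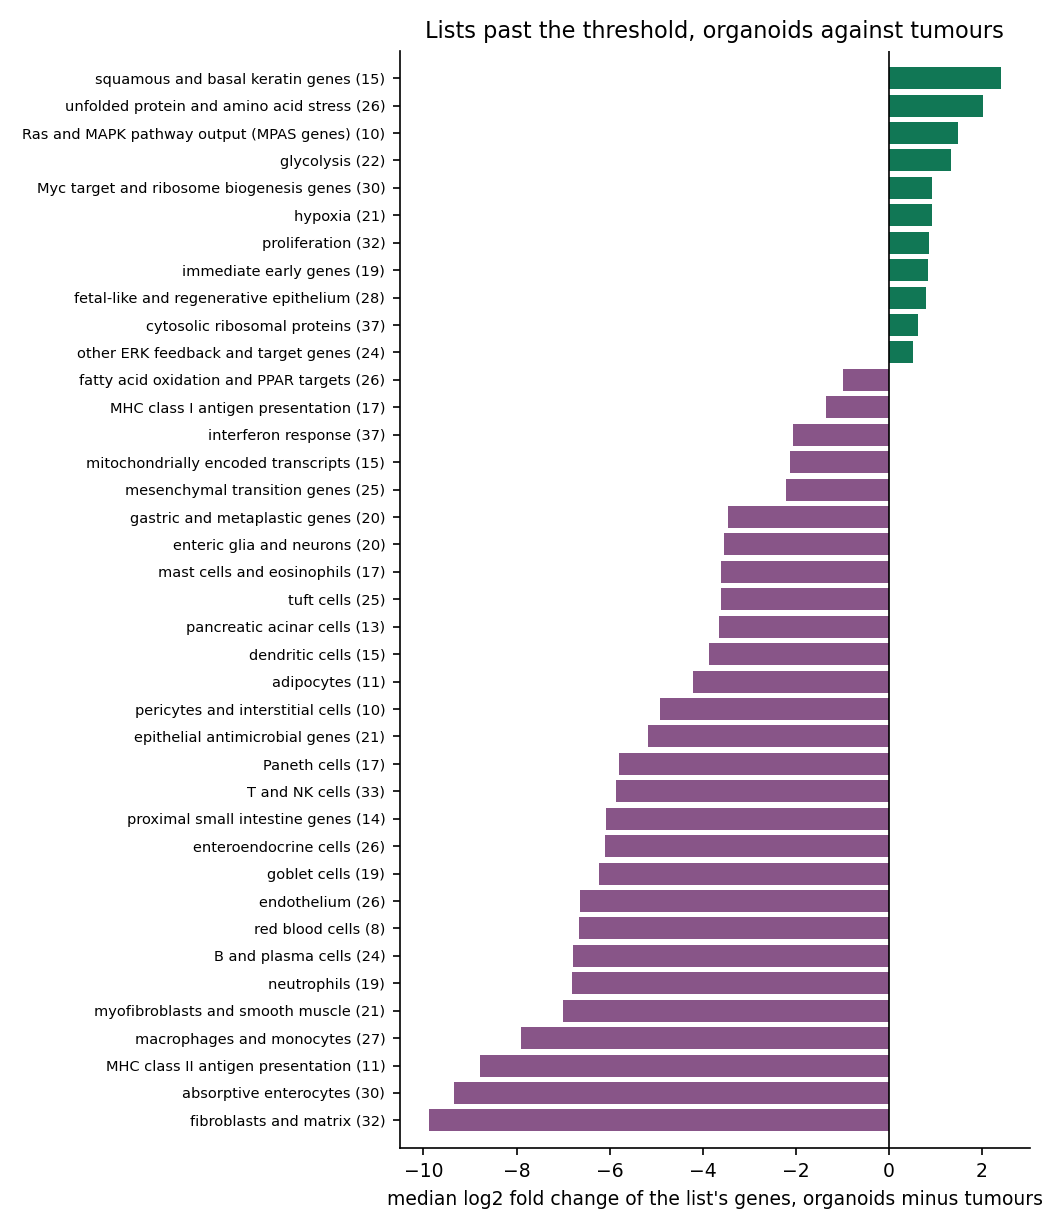
Median log2 fold change (organoids minus tumours, horizontal axis) of the genes of each of the 39 lists past the threshold with a preset correlation, with the number of genes tested in brackets and genes of 0 counts in organoids set at their bound. Bars reach -9.89 for fibroblast and matrix genes and 2.41 for squamous and basal keratin genes.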

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

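The tests of KPN tumours 2 and 4, of non-epithelial share, of sex in the organoids and of the labels of KPN organoid 4 and KPN tumour 1 were chosen after the results were seen. Of 300 sets of values within a group, 54 had a library far from the others of its group, where about 1 in 20, or 15, would by chance. The value given after each gene is the gap of that library to its nearest neighbour divided by the whole range of the group.

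KPN organoid 4 stood apart from the other KPN organoids in 10 of its 11 cases. It held less Mafb (0.94) and more of the differentiation genes Fabp2 (0.922), Aldob (0.957), Alpi (0.951), Muc13 (0.967), Tff3 (0.945) and Lyz1 (0.974), the gastric gene Gkn3 (0.896), the stem cell gene Ascl2 (0.865) and Atoh1 (1, from 2 counts). Among all organoids it alone held H2-Aa (1, from 1 count).

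The lists of enterocytes, goblet cells, Paneth cells, proximal small intestine, fatty acid oxidation and junction genes were higher in KPNKF organoids with a preset correlation, and none passed with an estimated one (adjusted p = 0.178 to 0.381). With sex in the model 6 of the 6 passed in the same direction, again with a preset correlation. Since 21 of 35 splits of the organoid libraries, the real one included, pass as many lists as the real labels, this hardly tests labelled sex as the cause. Of the lists lower in KPNKF organoids, 3 of 5 (Notch target, ribosomal protein and heat shock genes) lost their call with sex in the model. KPN organoid 4 had r of 0.935 to 0.952 with KPNKF and 0.874 to 0.902 with other KPN organoids. Of genes edgeR called without it, it lay nearer to the KPNKF mean in 76.2% (log2 CPM) and 52.4% (CPM). Both lay between the bounds for and against a wrong label, the second closer to that against, and the scale was not preset. A wrong label, a mixed culture and a KPN culture in a more differentiated state cannot be told apart, because the counts do not separate the Kras alleles. The loss of the remaining Kras allele stays open as a biological explanation of the difference between the groups. 

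KPN tumour 2 stood apart from the other KPN tumours in the summed share of CT010467.1, Lars2, Gm23935, mt-Rnr1 and mt-Rnr2 (0.957, at 27.6% against 0.285% to 1.46%), in low Kras (0.895) and in high Tyrobp (0.882), Rpl32 (0.886), Rps27 (0.869) and Hist1h1e (0.907). KPN tumour 4 stood apart among all tumours in high Igha (0.689), Fabp1 (0.822), Cyp3a25 (0.836), Apoa1 (0.622), Sis (0.704), Chga (0.879), Olfm4 (0.683) and mt-Atp6 (0.782). Within the KPN tumours it had a low score for fetal-like genes (0.856, at 5.14 against 7.51 to 7.91) and for neutrophil genes (0.894, at 0.52 against 3.72 to 4.1). The distal small intestine score was 5.03 and 4.45 in KPN tumours 3 and 4 and -0.1 to 2.71 in the other tumours, and the library name of KPN tumour 2 alone carries a mark for a proximal site.

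The tumour pattern has 7 lists, with B and plasma cell, T and NK cell, macrophage and neutrophil genes lower and Wnt target, stem cell and proliferation genes higher in KPNKF with a preset correlation, and none past the threshold with an estimated one (adjusted p = 0.65 to 0.662). With a preset correlation 7 of the 7 passed in the same direction without KPN tumour 2 and 6 without KPN tumour 4 (T and NK cells at 0.0562). Since other splits pass as many lists, this hardly tests either library as the cause. The 2 libraries do carry much of the epithelial part, since without both the medians fell from 0.90 to 0.37 for Wnt target, from 0.86 to 0.31 for stem cell and from 0.56 to 0.31 for proliferation genes. A larger share of non-epithelial tissue in the KPN tumours would lower all such lists in KPNKF, whereas 4 of 12 were lower and 2 higher (mast cells and eosinophils, enteric glia and neurons), again with a preset correlation only. Tissue composition, intestinal site, name series and genotype cannot be told apart on these values, and tumour stage was not tested. KPN tumour 1 lay nearer to the KPNKF mean than to that of KPN tumours 2 to 4 in 93.3% of the 3445 genes compared, those at an unadjusted p under 0.05 without it. A wrong Kras label of this library would give such a share. So would unusual tissue in KPN tumours 2 and 4, which make up most of the mean it was set against, or a state it shares with KPNKF tumours, and the label stays open. The test is not specific, since KPNKF tumour 1 lay nearer to the KPN mean in 68.9% and KPN tumour 4 nearer to the KPNKF mean in 69.8% of theirs. Of the 7 lists KPN tumour 1 scored outside the KPNKF range for B and plasma cells, neutrophils and macrophages. It scored inside for the others. Without it all 7 passed in the same direction (preset correlation), but as other splits pass as many, this hardly tests its label.

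KPN tumour 1 was the highest of the KPN tumours in Ascl2 (0.951), Rnf43 (0.899), Bcl7a (0.934) and the B cell genes Pax5 (0.867) and Cd19 (0.859). KPN tumour 3 was the highest in Fabp6 (0.999), Nrarp (0.837) and Tff3 (0.848), and of all tumours in Adm2 (0.581). Of the KPNKF tumours, number 1 was the lowest in Hras (0.874), Mcm4 (0.947) and the proliferation score (0.856) and the highest in Tyrobp (0.859), Flot1 (0.963) and Nkd2 (0.916). Number 2 was the highest in Osr2 (0.945) and the distal small intestine score (0.858) and the lowest in Aldob (0.886), and number 4 the highest in Glp1r (0.917) and Spry4 (0.83). KPN organoid 2 had the lowest Wnt target score of the KPN organoids (0.86, at 2.31 against 5.14 to 5.6) and the highest Myc (0.734) and Olfm4 (0.634) of all organoids, and KPN organoid 3 the highest Mcpt1 of its group (0.937). KPNKF organoid 1 had the highest Apoa1 (0.731), and KPNKF organoid 2 the highest Fabp1 (0.963) and Sis (0.702), of all organoids.

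The effect of the Kras genotype differed between organoids and tumours for 20 lists by camera with a preset correlation, and for 0 with an estimated one. More positive in organoids were goblet cells (adjusted p = 3.75e-08), nuclear oxidative phosphorylation (3.53e-06), ribosomal proteins (3.15e-05), histones (4.76e-05), fatty acid oxidation (0.000108), distal small intestine (0.000723), absorptive enterocytes (0.0012), unfolded protein and amino acid stress (0.00172), interferon response (0.0223), antimicrobial genes (0.0244), pancreatic acinar genes (0.0403), mitochondrially encoded transcripts (0.0432) and enteroendocrine cells (0.0478). More positive in tumours were proliferation (9.14e-06), Myc targets and ribosome biogenesis (0.00126), Wnt targets (0.00136), mast cells and eosinophils (0.00276), MPAS genes (0.0045), cholesterol synthesis (0.0183) and pericytes and interstitial cells (0.0319). With an estimated correlation these lists had an adjusted p of 0.748 to 0.86. Single libraries were needed for some calls, given with the adjusted p without the library. KPN organoid 1 was needed for enteroendocrine cells (0.0956), interferon response (0.0886), antimicrobial genes (0.0934), pericytes (0.175), acinar genes (0.0721) and mitochondrially encoded transcripts (0.0886). KPN organoid 2 was needed for Myc targets (0.158), enteroendocrine cells (0.0531), interferon response (0.335) and acinar genes (0.128). KPN organoid 3 was needed for cholesterol synthesis (0.151) and mitochondrially encoded transcripts (0.165). KPN organoid 4 was needed for MPAS genes (0.0632), cholesterol synthesis (0.0648), interferon response (0.0828), antimicrobial genes (0.0632), pericytes (0.0943) and mitochondrially encoded transcripts (0.0822). KPN tumour 1 was needed for enteroendocrine cells (0.153), antimicrobial genes (0.0774) and acinar genes (0.125). KPN tumour 2 was needed for cholesterol synthesis (0.762) and ribosomal proteins (0.861). KPN tumour 3 was needed for antimicrobial genes (0.0897) and acinar genes (0.0739). KPN tumour 4 was needed for MPAS genes (0.092), enterocytes (0.868), enteroendocrine cells (0.35), fatty acid oxidation (0.145), interferon response (0.0778), pericytes (0.184), acinar genes (0.125) and mitochondrially encoded transcripts (0.776). KPNKF organoid 1 was needed for enteroendocrine cells (0.0694), antimicrobial genes (0.133) and mitochondrially encoded transcripts (0.0582). KPNKF organoid 2 was needed for Wnt targets (0.0789), cholesterol synthesis (0.0789), unfolded protein stress (0.053), pericytes (0.0525) and mitochondrially encoded transcripts (0.362). KPNKF organoid 3 was needed for cholesterol synthesis (0.057), interferon response (0.696), antimicrobial genes (0.0736) and acinar genes (0.156). KPNKF tumour 1 was needed for pericytes (0.0608). KPNKF tumour 2 was needed for enteroendocrine cells (0.0943), cholesterol synthesis (0.0857) and mitochondrially encoded transcripts (0.14). KPNKF tumour 3 was needed for interferon response (0.108). KPNKF tumour 4 was needed for antimicrobial genes (0.0691) and acinar genes (0.0595). The interferon response list had the opposite direction without KPNKF organoid 3. With labelled sex in the model interferon response (0.538), Myc targets (0.078), acinar genes (0.0522) and mitochondrially encoded transcripts (0.0856) were not called.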

How the results depend on the processing

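The alternatives that leave out KPN tumours 2 and 4 together, or 5 genes (4 of ribosomal RNA or small RNA type and Lars2), and the tests on them, were chosen after seeing the data, and the others were planned. Of the recomputed answers to the comparisons 193 stayed close to their value and 20 moved, where close means a count within 1.5 times its value, a Kras fold change on the same side of the threshold and a correlation within 0.127, the SD over the splits. Named genes kept their side of the threshold in 2211 values and newly passed in 55. Lists kept theirs in 2008, lost the call in 288 and newly passed in 20, and 4 calls changed direction. Counting uncalled lists, 9, 5, 9 and 5 values per comparison did. Where no cause is given, none was tested.

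DESeq2 called 30 genes in tumours, 118 in organoids and 57 for the difference of the genotype effect, where edgeR called 0 each. In simulated counts DESeq2 called 48 to 84 unchanged genes per comparison and edgeR 2 to 7, and DESeq2 recovered 53.7% to 92.5% of genes changed 4-fold and edgeR 26.9% to 74.6%. With all 15 libraries in a single fit, edgeR called 2 genes in organoids, and the fit then has more libraries to estimate the spread from. Within KPNKF alone 6248 genes differed between organoids and tumours, as a contrast of the KPNKF groups in the same fit of all 15 libraries.

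Camera with an estimated correlation passed 0 lists in tumours, 0 in organoids, 0 for the difference of the genotype effect and 2 for organoids against tumours. The test fry passed 0 in tumours, 2 in organoids and 0 for the difference of the genotype effect. At an unadjusted p under 0.05 in both comparisons 19 genes overlapped between tumours and organoids.

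With each library left out in turn, edgeR called 0 to 1 genes in tumours (1 without KPN tumour 1), 0 to 21 in organoids (21 without KPN organoid 4), 0 to 25 for the difference of the genotype effect (25 without KPN organoid 4, 1 without KPN tumour 1 or 3) and 9651 to 12066 for organoids against tumours. Lists past the threshold numbered 23 to 33, 13 to 24, 13 to 25 and 38 to 41, with 24 in organoids without KPNKF organoid 2 and 13 for the difference without KPN tumour 4. The correlation ranged from 0.01 (without KPN organoid 3) to 0.203 (without KPN tumour 4), with 0.017 without KPN tumour 2 and 0.07 without KPN tumour 3. The Kras log2 fold change ranged from 0.18 to 0.43 in tumours, lowest without KPN tumour 2, and from 0.02 to 0.29 in organoids, lowest without KPNKF organoid 1.

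In tumours the junction and keratin list had the opposite direction without KPN tumour 2 (adjusted p = 0.742, range over single libraries 3.75e-05 to 0.742), and the fatty acid oxidation list without KPN tumour 4 (0.703, range 2.32e-06 to 0.703). The metastasis-associated list had it without KPN tumours 2 and 4 (0.754), and for the difference of the genotype effect the interferon response list had it without KPNKF organoid 3 (0.696, range 2.48e-06 to 0.696). The cause was not tested. With CT010467.1, Lars2, Gm23935, mt-Rnr1 and mt-Rnr2 removed, edgeR called 0 genes in tumours and 27 lists passed.

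Replicate numbers, not labelled as sharing an animal or day, were tried as a block. With the block edgeR called 0 genes in tumours, 0 in organoids, 0 for the difference and 10016 for organoids against tumours, and 30, 22, 24 and 40 lists passed. The correlation of residuals between libraries of equal number was 0 to 0.22 in tumours and 0.04 to 0.24 in organoids, and 0.04 to 0.16 and -0.29 to 0.09 between organoids and tumours of KPN and KPNKF.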

Other observations

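The genes that separated KPNKF from KPN organoids once KPN organoid 4 was left out were named after their values were seen, as were the tests of the Ddx3y counts; the tests by other splits of the libraries were planned. Of 21 genes called then, 16 were higher in KPNKF. Hnf1a, a transcription factor gene of enterocytes, was at 0.19 CPM in KPN organoids 1 to 3, 12.1 CPM in KPN organoid 4 and 27.9 CPM in KPNKF organoids (log2 fold change 7.16, adjusted p = 0.00308). Heph, an iron oxidase gene of enterocytes, was at 0.828, 46.1 and 72.4 CPM, and Cdhr2 of the brush border at 4.52, 236 and 315 CPM. The hypoxia-induced gene Car9 was at 11.2, 284 and 240 CPM, and the adhesion gene Nectin3 at 0.72, 25.8 and 31.9 CPM. The claudin gene Cldn6 went the other way, at 152, 3.98 and 1.14 CPM, as did Pxdn at 44.4, 0.134 and 0.0861 CPM. Itga1 was an exception, with KPN organoid 4 at 0.936 CPM beside 0.835 CPM in the other KPN organoids and 8.33 CPM in KPNKF.

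The first principal component of the tumours held 63.7% of the variance and placed KPN tumour 2 at -115 and KPN tumour 4 at 52.8. In the organoids it held 43.8% and placed KPN organoid 4 at -30.7, on the side of the KPNKF organoids (-49.6 to -13.8), and the other KPN organoids at 36.4 to 56.5.

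Other splits of the same libraries were run for each count. For organoids against tumours the real labels gave 10626 genes and the highest other of the 100 splits 7659, so chance can be excluded for that count, with 1 split as large, the real one. For lists there, 39 passed and the highest other split gave 47, with 10 of 100 as large, so chance cannot be excluded. In tumours 27 lists passed (highest other 34, 15 of 35 splits as large), in organoids 15 (highest other 27, 21 of 35) and for the difference of the genotype effect 20 (highest other 30, 27 of 100), and the correlation was 0.106 (highest other 0.181, 11 of 35). Chance cannot be excluded for these 4 values. The real labels gave 0 genes in tumours (highest other 0), in organoids (highest other 34) and for the difference of the genotype effect (highest other 55). No count can be lower, so all splits were as large by construction (35 of 35, 35 of 35 and 100 of 100), and these 3 counts of splits say nothing about chance. The organoid split with 34 genes set KPN organoid 4 and the 3 KPNKF organoids against KPN organoids 1 to 3. The others gave 0 genes, except 11 in a split that also set KPN organoid 4 beside KPNKF organoids 2 and 3, and 1 in another. The split with 34 genes is what a wrong label of KPN organoid 4 would give, and equally a state it shares with KPNKF organoids, so it leaves that question open. For the difference of the genotype effect, the split with 55 genes points to a structure of the libraries whose cause was not tested.

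The labelled sex was compared with Xist and 4 Y-linked genes. KPNKF organoid 2, labelled male, held 0 counts of Ddx3y. A library from a female mouse in its place is excluded by Xist at 0.45 CPM, against 217.46 to 1046.67 CPM in libraries labelled female. Loss of the Y chromosome in the whole culture is excluded by 6675 counts over the 4 Y-linked genes, with 604 of Uty, 1935 of Kdm5d and 4136 of Eif2s3y. A loss or silencing of Ddx3y alone was not tested. KPN organoid 1, labelled male, held 264 counts of Xist (9.01 CPM) and 1135 counts of the Y-linked genes.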
